A study of Mus musculus with 7 samples.

How the data were processed

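The series profiled tissue microdissected from the suprachiasmatic nucleus (SCN), the hypothalamic nucleus that holds the central circadian clock, in mice of the DBA/2J strain and in a control strain. DBA/2J mice carry a mutation of Gpnmb, develop high intraocular pressure and lose retinal ganglion cells with age, so they serve as a model of glaucoma. The control strain, DBA/2J-Gpnmb+/SjJ, carries the functional allele. Of the 7 libraries, 4 were control (scn_cont_565, scn_cont_567, scn_cont_568 and scn_cont_570) and 3 were advanced glaucoma (scn_glauc_152, scn_glauc_153 and scn_glauc_154). The groups and the numbers come from the sample titles. The design text speaks of mice per group, so the libraries were taken as separate mice, and no number is shared between the groups. The genotype field of the labels reads WT in both groups and was not used to form them. Time of day, age, sex and library batch were not given in the sources used here.

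Per the labels' protocols, RNA was turned into barcoded libraries with the MERCURIUS kit for BRB-seq, a method that tags each sample's RNA with a barcode at the 3′ end of transcripts and pools the samples before sequencing. The deposited table holds raw counts per gene, whole numbers with a different total in each library. Per the submitters' processing notes, STAR, HTSeq, featureCounts and DESeq2 were used and the genome build was mm10; their roles, versions and settings were not given in the sources used here. Neither the annotation release, the strand setting, nor whether unique molecular identifiers were collapsed was given in the sources used here. Counts may therefore be reads and not independent molecules, and the counts of genes that overlap cannot be split by strand. A 3′ count also reads the end of a transcript and not its whole length.

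The table lists 55487 genes by Ensembl identifier, of which 24908 had a count in any library. A symbol was found for 55141 identifiers in a gene name table, and the 346 without one held 0.0291% of the counts. Coordinates were taken from the GENCODE annotation of GRCm38, the same assembly as mm10. Every column of the table was used.

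Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group at its defaults, which kept 14020. Libraries were scaled with TMM factors, and the quasi-likelihood test was fitted with robust estimation and with the group as the only term. P-values were adjusted by Benjamini-Hochberg over all 14020 genes, at a threshold of 0.05 with no fold threshold. Levels are given as CPM, the deposited counts of a gene scaled to a common library total after TMM scaling. Log2 fold changes are advanced glaucoma over control. Their standard error (SE) was taken as the size of the log2 fold change over the root of the F statistic, and 95% intervals use the t quantile at the fit's degrees of freedom.

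Before the data were examined, 28 gene lists were fixed: SCN neuropeptides, receptors and identity genes, the core clock, light-responsive immediate early genes, and 25 lists of pathways, other cell types and neighbouring tissue. Each was tested against all other genes with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided and adjusted over the 28 lists. The same test with a correlation estimated from the data was an alternative. Sex-linked genes were read per library and not tested.

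The genes named were set by a rule fixed before the data were examined. It takes Gpnmb in every library, Clock, Arntl, Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Dbp, Vip and Avp whatever their test, the 12 genes with the smallest adjusted p in each direction, and up to 4 members per list that passed, or up to 2 with the smallest p where none did. Names starting with Gm and digits or ending in Rik, and identifiers with no symbol, were to be counted only, and none was among the genes that passed. Six3, Six6, Grp, Scg2, Vipr2, Penk, Syt10, Lhx2, Zic1, Zic2, Zic5, Bsx, Gsx1, Ghrh, Cartpt, Oxt, Pomc, Agrp, Nptx1, Rorb and Dusp1 fell outside the rule and were chosen after their values were seen. A few genes that the rule takes are not reported here, though the counts of named genes include them.

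Group differences in a single value were tested with two-sided exact permutation tests over the 35 splits of 7 libraries into 4 and 3, whose smallest possible p is 0.0286. The alternatives fixed before the data were examined were DESeq2's median-of-ratios factors (RLE) and plain library size in place of TMM, no filter on low counts, a mean of at least 10 CPM, the mean of the myelin list as a covariate, DESeq2 1.42.0, limma-voom with sample weights, and leaving out each library in turn. Sex as a covariate was planned only if both sexes were seen.

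The scripts were tested on simulated data: 5 sets of counts drawn for the 14020 genes from the real means and library sizes, with 200 genes changed in each. In these, the comparison of advanced glaucoma with control recovered 67.6% of genes changed 2-fold and 93.8% of those changed 4-fold, and 6.94% of calls were unchanged genes. A list shifted by 0.5 on the log2 scale was called in 5 of 5 sets with either correlation. The simulated genes varied independently of each other, whereas the estimated correlation was 0.740 in the real myelin list and 0.0778 in the core clock list. This recovery of a shifted list therefore does not carry over to lists of correlated genes.

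Library totals ran from 2174456 to 5285093 counts, so 1 CPM stood for 2.17 to 5.29 counts. A floor of 3 counts corresponds to 0.540 to 1.49 CPM depending on the library, and this floor covers counting error only.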

Results

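The suprachiasmatic nucleus (SCN) of the hypothalamus receives light signals from the retina through retinal ganglion cells and keeps daily time for the body. RNA from SCN microdissections was counted in 4 control and 3 advanced glaucoma libraries to ask how the central clock tissue differs after glaucoma. The libraries are named by their titles. The control libraries scn_cont_565, scn_cont_567, scn_cont_568 and scn_cont_570 held 2174456, 3290823, 4019857 and 5285093 counts. The advanced glaucoma libraries scn_glauc_152, scn_glauc_153 and scn_glauc_154 held 5118764, 4655862 and 3585907 counts. Mean depth was 3692557 ± 1305031 counts in control (SD, n = 4) and 4453511 ± 786207 in advanced glaucoma (SD, n = 3; exact permutation p = 0.429, two-sided). Mitochondrial transcripts took 15.9 ± 2.83% of counts in control and 15.8 ± 0.663% in advanced glaucoma (exact permutation p = 0.971, n = 4 and n = 3). Mitochondrial mt-Rnr2 was the top gene in each library, at 4.84% to 8.77% of counts. Pearson correlations between pairs of libraries on log2 CPM across genes ran from 0.945 to 0.974. No pair agreed within counting noise, with a chi-square over its degrees of freedom of 4.47 to 12.3. That noise covers counting error only, so the 7 libraries were taken as separate samples from the design and not from this test. Xist had at most 3 counts in any library and the Y-linked gene Ddx3y had 175 to 561, so the libraries were of one sex.

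The first principal component of log2 CPM held 29.1% of the variance and set scn_cont_565, the shallowest library, at -50.81 apart from the other libraries, which lay between -1.61 and 20.4. The second component held 19.99% and placed scn_cont_567, scn_cont_568 and scn_cont_570 between 15.2 and 25.7. On that component the advanced glaucoma libraries lay between -28.58 and -7.44, with scn_cont_565 at -12.04 among them.

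Gpnmb, the gene whose mutation separates the strains, was close to undetected in the SCN of both groups. The gene (chromosome 6, 49036546 to 49070929, mm10) had 0, 1, 0 and 2 counts in scn_cont_565, scn_cont_567, scn_cont_568 and scn_cont_570, and 1, 1 and 0 counts in scn_glauc_152, scn_glauc_153 and scn_glauc_154. Its level was 0.167 ± 0.194 CPM in control and 0.137 ± 0.119 CPM in advanced glaucoma (SD, n = 4 and n = 3; exact permutation p = 0.914). Every library was at or under the floor of 3 counts, so no fold is given and the labels could not be checked with this gene.

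The advanced glaucoma libraries held far less of several transcripts that mark SCN neurons. Of 14020 genes tested, 66 differed between the groups at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 53 were lower and 13 higher in advanced glaucoma. The genes with the smallest adjusted p were Rgs16, a regulator of G protein signalling with a daily rhythm in the SCN, Rasl11b, a small GTPase-like gene, and Rora, a nuclear receptor of the clock. Rgs16 fell 5.70-fold, from 89.9 ± 12.0 CPM in control to 15.7 ± 4.90 CPM in advanced glaucoma (SD, n = 4 and n = 3), and Rasl11b fell 6.21-fold, from 46.9 ± 11.4 to 7.45 ± 0.538 CPM. The changed genes included 25 with more than a 2-fold difference. In 64 of the 66, the libraries of the groups did not overlap, which held for 8.02% of all tested genes against 5.71% expected by chance. At an unadjusted p under 0.05 the count was 1150.

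Genes that define SCN peptides, receptors and cell identity were lower as a group. Of 27 measured members, 12 were lower and 0 higher over all genes tested; adjusted over the list alone, 15 were lower and 1, the transcription factor gene Lhx2, was higher. The list fell in the set test (camera, adjusted p = 1.91e-16), and the call held with an estimated correlation (adjusted p = 0.0393). Vip, the peptide of the retinorecipient SCN core that couples clock neurons, fell the most: 42.6-fold, from 112 ± 37.7 CPM in control to 2.69 ± 1.38 CPM in advanced glaucoma (SD, n = 4 and n = 3; log2 fold change -5.41, SE 0.484, 95% interval -6.58 to -4.25, adjusted p = 0.00884 by edgeR). Vip (ENSMUSG00000019772, chromosome 10, 5639218 to 5647617) had 211 to 563 counts per control library and 6, 14 and 14 counts in scn_glauc_152, scn_glauc_153 and scn_glauc_154. Nms, neuromedin S, which marks a large share of SCN clock neurons, fell 12.2-fold, from 38.2 ± 10.9 to 2.98 ± 1.63 CPM (adjusted p = 7.34e-06 by edgeR). Prokr2, the receptor for the SCN output peptide prokineticin 2, fell 15.8-fold, from 21.0 ± 9.37 to 1.28 ± 0.796 CPM, and rested on 3, 10 and 4 counts in the advanced glaucoma libraries. Prok2, which encodes that peptide, fell 6.46-fold, from 13.1 ± 4.59 to 1.99 ± 1.05 CPM.

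Grp, gastrin-releasing peptide of the SCN core, fell 5.46-fold, from 32.0 ± 11.7 to 5.52 ± 3.36 CPM. Among transcription factor genes, Lhx1 fell by 1.75 (SE 0.247), Six6 by 0.86 (SE 0.153), Zfhx3 by 0.86 (SE 0.114) and Six3 by 0.64 (SE 0.111) on the log2 scale. Six6, Zfhx3 and Six3 each overlap another tested gene on the opposite strand, and the strand setting of the counts is unknown. Scg2, a secretogranin precursor of secreted peptides, fell by 0.43 (SE 0.0904). Members that did not pass over all genes included Vipr2, the receptor for VIP, at 27.2 ± 12.6 CPM in control and 6.26 ± 2.74 CPM in advanced glaucoma (log2 fold change -2.12, adjusted p = 0.109 by edgeR). Vipr2 passed with no filter on low counts, with DESeq2 and without scn_cont_565 (0.04965) or scn_cont_567 (2.10e-04), in a range of 1.56e-13 to 0.814 over its alternatives. Penk had a log2 fold change of -0.44 (adjusted p = 0.0722 by edgeR) and Syt10, a synaptotagmin gene enriched in the SCN, one of -1.13 (adjusted p = 0.187), with 0.0104 to 0.903 and 0.0211 to 0.462 over their alternatives; Penk passed with no filter, with DESeq2 and without scn_cont_567, and Syt10 with no filter. Avp, vasopressin, which is made in the SCN shell and also in the neighbouring paraventricular and supraoptic nuclei, varied widely: 3205 ± 2475 CPM in control and 1786 ± 1565 CPM in advanced glaucoma (SD, n = 4 and n = 3; log2 fold change -0.84, 95% interval -3.80 to 2.11, adjusted p = 0.929 by edgeR). Library scn_glauc_154 had 126 CPM of Avp, while scn_glauc_152 and scn_glauc_153 had 1998 and 3234 CPM.

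**Figure D1:**
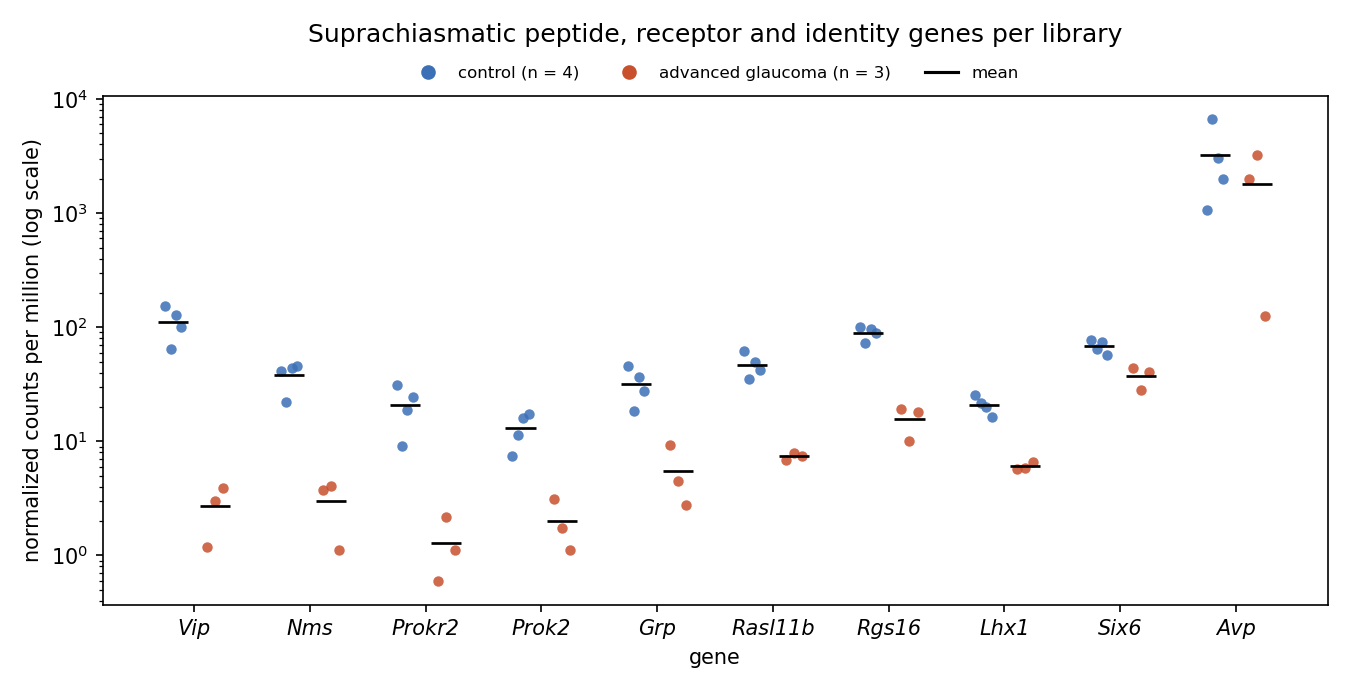
Normalized counts (CPM) on a log axis for 10 SCN genes, with 1 point per library, 4 control and 3 advanced glaucoma, and the group mean as a bar. For Vip the control libraries lie between 64.6 and 152.4 CPM and the advanced glaucoma libraries between 1.18 and 3.88 CPM, while for Avp the groups overlap.

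Nkx2-1, a transcription factor gene of the ventral and tuberal hypothalamus (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908), was 2.26-fold higher, at 21.7 ± 6.83 CPM in control and 48.6 ± 7.66 CPM in advanced glaucoma (SD, n = 4 and n = 3; adjusted p = 0.00819 by edgeR). Pmch, the melanin-concentrating hormone precursor of the lateral hypothalamus, was at 11.9 to 25.3 CPM in the control libraries and at 285, 1331 and 202 CPM in scn_glauc_152, scn_glauc_153 and scn_glauc_154 (log2 fold change 5.17, adjusted p = 0.184 by edgeR). Ghrh, growth hormone-releasing hormone of the arcuate region, was at 16.2 ± 8.10 and 60.5 ± 20.1 CPM (log2 fold change 1.91, adjusted p = 0.215 by edgeR). Neither passed in the main test, but over the alternatives Pmch ran from 4.09e-08 to 0.483 and passed with DESeq2 and without scn_glauc_153 (6.24e-04). Ghrh ran from 6.79e-06 to 0.552 and passed with no filter on low counts, with DESeq2 and without scn_cont_567 (0.0175) or scn_glauc_153 (0.0370). The mean log2 CPM of the myelin list, relative to its mean in control, was -0.60, -0.03 and -1.003 in scn_glauc_152, scn_glauc_153 and scn_glauc_154, where the control libraries ran from -0.22 to 0.12 (camera adjusted p = 0.395 with an estimated correlation). The Vip call was lost without scn_glauc_153 (adjusted p = 0.0643 by edgeR), without scn_glauc_154 (0.0620), with limma-voom weights (0.126) and with the myelin list as a covariate (0.109), in a range of 1.37e-24 to 0.126 over its alternatives. With that covariate 6 of the 12 lower members kept their call (Rgs16, Rasl11b, Nms, Prokr2, Lhx1 and Six6), Grp also lost it without scn_glauc_153 (0.110), and Scg2 lost it without any of scn_cont_568 and scn_cont_570 and scn_glauc_152, scn_glauc_153 and scn_glauc_154.

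**Figure D2:**
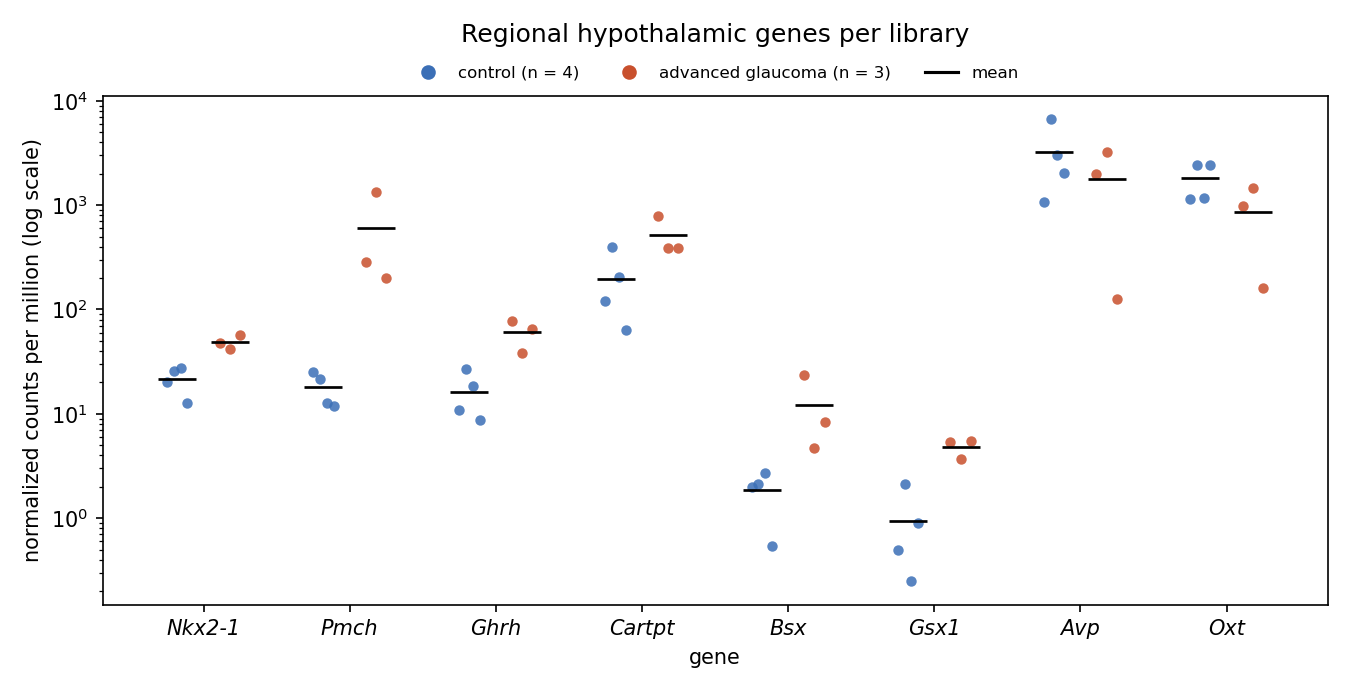
Normalized counts (CPM) on a log axis for 8 genes of hypothalamic regions around the SCN, with 1 point per library, 4 control and 3 advanced glaucoma, and the group mean as a bar. Nkx2-1 lies between 12.6 and 27.8 CPM in control and between 41.6 and 56.8 CPM in advanced glaucoma, and Pmch reaches 1331 CPM in scn_glauc_153.

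Among the other genes with the smallest adjusted p in the lower direction, Vgf, a secreted neuropeptide precursor, fell 1.98-fold, from 348 ± 60.7 to 177 ± 6.11 CPM (adjusted p = 2.82e-05 by edgeR). Igfbp5, which encodes a binding protein for insulin-like growth factors, fell 1.87-fold, from 248 ± 43.3 to 132 ± 13.7 CPM (adjusted p = 1.59e-04). The zinc finger transcription factor gene Zic4 fell by 2.195 (SE 0.291) on the log2 scale. Zic4 overlaps Zic1 on the opposite strand, and the strand setting of the counts is unknown. With the myelin list as a covariate, Zic4 lost its call (adjusted p = 0.109 by edgeR).

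The genes that were higher in advanced glaucoma changed less. The 12 with the smallest adjusted p were Ets2, Sfta3-ps, Nkx2-1, Nefl, Fxyd7, Pdzph1, Ecel1, Pld5, Wfs1, Necab2, Plxna2 and Npy2r, and Nptx1 was the remaining one. Ets2, an ETS family transcription factor gene, rose 1.63-fold, from 74.0 ± 9.68 to 120 ± 17.7 CPM (SD, n = 4 and n = 3; adjusted p = 0.00341 by edgeR). Sfta3-ps, a non-coding transcript beside Nkx2-1 on chromosome 12, rose 2.88-fold, from 7.55 ± 3.46 to 22.3 ± 4.40 CPM (adjusted p = 0.00567). Pdzph1 had the largest fold of the 12, 3.33, at 3.15 ± 1.43 and 10.5 ± 2.30 CPM (adjusted p = 0.0184). Nefl, the light neurofilament subunit, rose 1.55-fold, from 181 ± 12.7 to 282 ± 63.4 CPM (adjusted p = 0.00884), and it overlaps Nefm on the opposite strand. Npy2r, a receptor for neuropeptide Y, rose 1.69-fold, from 22.1 ± 2.85 to 37.1 ± 6.35 CPM (adjusted p = 0.0420). The log2 fold changes of Fxyd7, Ecel1, Pld5, Wfs1, Necab2 and Plxna2 lay between 0.55 and 0.79, and that of Nptx1 was 0.62. Of the 12, Ets2 alone kept its call without each library in turn, and Nefl alone kept it with the myelin list as a covariate. Nptx1 kept its call in 2 of the 7 alternatives that used all libraries and in 2 of the 7 fits with a library left out. Nkx2-1 lost its call without scn_cont_565, without scn_glauc_154 and with that covariate, at adjusted p of 3.51e-09 to 0.412 over its alternatives.

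The count of changed genes depended on single libraries and on the model. It was 33 without scn_cont_570, 28 without scn_glauc_154, 15 with the myelin list as a covariate and 202 with no filter on low counts, where 53.5% of calls were lower against 80.3% in the main test.

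The core clock genes, which form the transcriptional feedback loop of the circadian clock, did not pass the set test as a group. Of 24 measured members, 1 was lower over all genes tested, Rora, and 0 were higher; adjusted over the list alone, 5 were lower (Rora, Nr1d1, Per2, Rorb and Dbp) and 0 higher. The set test gave an adjusted p of 0.114 (camera), and 0.527 with an estimated correlation. Rora, a nuclear receptor that activates Arntl transcription, fell 2.22-fold, from 163 ± 13.9 CPM in control to 73.4 ± 4.41 CPM in advanced glaucoma (SD, n = 4 and n = 3; adjusted p = 3.31e-07 by edgeR). Rora (chromosome 9, 68653786 to 69388246) was lower in each of the 3 advanced glaucoma libraries, at 69.5 to 78.2 CPM, than in any control library, at 143 to 173 CPM. In these libraries the mean log2 CPM of the SCN list was -1.32 to -1.06 relative to its mean in control. Whether Rora or other clock genes fell apart from the SCN list was not tested.

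None of the other core clock genes passed over all genes in the main test. Nr1d1, the repressor that competes with ROR receptors, was at 68.4 ± 4.96 and 47.8 ± 2.74 CPM (log2 fold change -0.52, adjusted p = 0.0566 by edgeR), with adjusted p of 0.0275 to 0.432 over its alternatives. It passed with no filter on low counts, with a mean of at least 10 CPM and with DESeq2. Per2, a negative limb gene of the loop, was at 31.8 ± 7.21 and 18.9 ± 6.004 CPM (log2 fold change -0.73, adjusted p = 0.185), with 0.0286 to 0.859 over its alternatives. It passed with no filter and without scn_glauc_152. Of the list, 4 members were lower with no filter and 3 with DESeq2, against 1 in the main test. Rorb had a log2 fold change of -0.72 (adjusted p = 0.186, and 1.72e-04 to 0.859 over its alternatives, past the threshold with no filter, with DESeq2 and without scn_glauc_152) and Dbp, a clock output gene, one of -0.38 (adjusted p = 0.257). Nr1d1 overlaps Thra and Dbp overlaps Sphk2, each on the opposite strand, and Per3 overlaps Camta1. The positive limb genes Clock and Arntl had log2 fold changes of -0.15 (95% interval -0.39 to 0.08) and 0.02 (95% interval -0.44 to 0.48). For Per1, Per3, Cry1 and Cry2 the log2 fold changes were -0.32, 0.26, 0.16 and 0.05, with intervals of -0.77 to 0.13, -0.03 to 0.56, -0.32 to 0.65 and -0.21 to 0.30. The set test passed with a mean of at least 10 CPM (adjusted p = 0.00590, camera) and without scn_glauc_152 (adjusted p = 0.0368). The labels give no time of day, so a difference in rhythm was not analysed here.

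**Figure D3:**
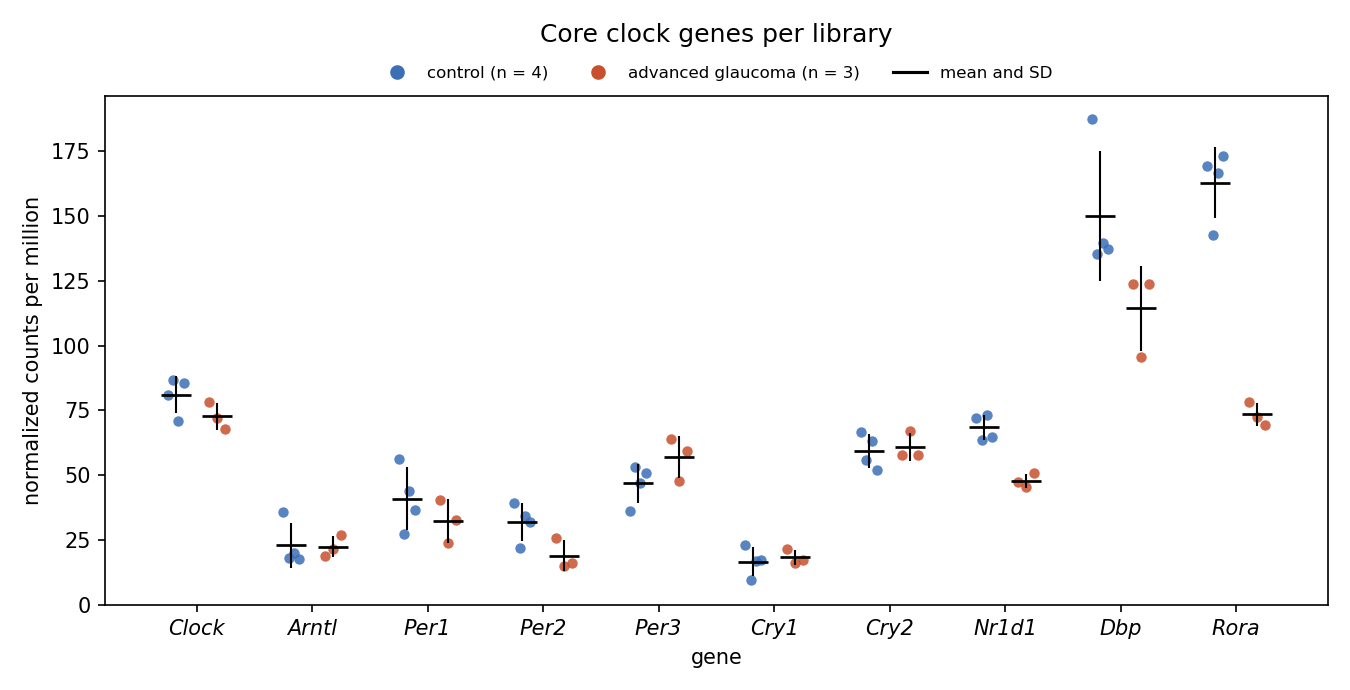
Normalized counts (CPM) for 10 core clock genes, with 1 point per library, 4 control and 3 advanced glaucoma, the group mean as a horizontal bar and the SD as a vertical line. Rora lies between 143 and 173 CPM in control and between 69.5 and 78.2 CPM in advanced glaucoma, and the groups overlap for Clock, Arntl, Per1, Per2, Per3, Cry1 and Cry2.

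Light-responsive immediate early genes, which light pulses induce in the SCN through the retinal input, were lower as a group in the set test with a preset correlation (camera, adjusted p = 5.11e-04). The call was lost with an estimated correlation (adjusted p = 0.266 with an estimated correlation). The SCN list was lower in the same libraries, with a mean log2 CPM of -1.32 to -1.06 relative to its mean in control, and whether the light-responsive genes fell apart from that was not tested. Of 28 measured members, 3 were lower (Vgf, Fos and Nr4a3) and 0 higher over all genes tested; adjusted over the list alone, 4 were lower, with Dusp1 added. Fos, the immediate early gene most used as a marker of neuronal activation, fell 1.96-fold, from 42.2 ± 2.28 to 21.6 ± 2.26 CPM (SD, n = 4 and n = 3; adjusted p = 0.00160 by edgeR). Nr4a3, a nuclear receptor induced by activity, fell 2.40-fold, from 19.0 ± 3.88 to 7.64 ± 2.32 CPM (adjusted p = 0.0176). Fos and Nr4a3 lost their calls with the myelin list as a covariate (adjusted p = 0.109 and 0.616), and Nr4a3 also without scn_cont_567 or scn_glauc_154, at adjusted p of up to 0.157.

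Of the 25 other lists, 7 passed with the preset correlation, 5 lower and 2 higher, and 0 passed with an estimated one. Of the 35 splits of the libraries into 4 and 3, 10 gave 7 or more such lists, the real one included. Chance is therefore not argued against for that count. All 27 measured myelin genes had a negative log2 fold change, with a median of -0.48 (adjusted p = 5.12e-13, camera; adjusted p = 0.395 with an estimated correlation), but 1 member, Apod, a lipocalin of oligodendrocytes, passed alone (log2 fold change -0.48, adjusted p = 0.0324 by edgeR). The astrocyte list was lower (adjusted p = 4.32e-04; adjusted p = 0.193 with an estimated correlation), and 2 of its 23 members fell: the water channel gene Aqp4, from 111 ± 11.5 to 72.9 ± 8.32 CPM, and Id4, from 200 ± 21.6 to 139 ± 14.6 CPM. The reactive astrocyte list was lower (adjusted p = 5.11e-04; adjusted p = 0.395 with an estimated correlation), with Aspg, an asparaginase gene, past the threshold among 18 members at 11.2 ± 5.91 and 3.53 ± 0.700 CPM. The microglia list was lower (adjusted p = 0.00120; adjusted p = 0.317 with an estimated correlation) with 0 of 23 members past, and its leading members were Ctss and Ly86 at log2 fold changes of -0.38 and -0.50. The list of fibroblasts and meninges was lower (adjusted p = 4.50e-05; adjusted p = 0.387 with an estimated correlation), with 1 of 17 members past, Aldh1a2, a retinoic acid synthesis enzyme that fell from 16.4 ± 2.00 to 6.26 ± 3.02 CPM. The reactive astrocyte call was lost without scn_glauc_153 (adjusted p = 0.0687) and the microglia call without scn_glauc_152 (0.0890). With the myelin list as a covariate the astrocyte list did not pass (0.0591). Among single members, Apod, Aqp4, Id4 and Aspg lost their calls with that covariate. Aqp4 also lost its call without scn_glauc_152, and Id4 without scn_cont_570, scn_glauc_153 or scn_glauc_154. With a library left out, Apod kept its call in 2 of 7 fits, Aldh1a2 in 3 and Aspg in 1. Aspg also lost it with plain library size and limma-voom weights, at adjusted p of up to 0.626 over its alternatives.

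The list of the paraventricular, supraoptic and arcuate nuclei was higher (adjusted p = 0.00529, camera; adjusted p = 0.395 with an estimated correlation). None of its 19 members passed over all genes, while adjusted over the list alone 4 were higher and 1 lower. By sign 15 members were higher and 4 lower, with Oxt among the lower ones (log2 fold change -1.06). The mean log2 CPM of the list, relative to its mean in control, overlapped between the groups. It was 0.69, 0.86 and 0.24 in scn_glauc_152, scn_glauc_153 and scn_glauc_154, and -0.52 to 0.56 in the control libraries. Its leading members by p were Th, tyrosine hydroxylase of dopamine synthesis, at 39.4 ± 10.4 and 59.0 ± 9.20 CPM (adjusted p = 0.184 by edgeR, and 0.00972 to 0.969 over its alternatives, past the threshold with no filter and without scn_cont_567), and Pmch. The list of glutamate and PACAP signalling, which carries the retinal input, was higher (adjusted p = 0.0158; adjusted p = 0.371 with an estimated correlation) with 0 of 29 members past, and Gria1 among its leading members at a log2 fold change of 0.31. Without scn_glauc_153 neither list passed (adjusted p = 0.0904 and 0.133), and without scn_glauc_154 the glutamate and PACAP list did not (0.0663).

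The remaining 18 lists did not pass with the preset correlation. Signs of inflammation lay among them, with adjusted p of 0.256 for reactive and phagocytic microglia (Apoe and Cd63 at log2 fold changes of -0.24 and -0.21), 0.194 for complement (C3 and C4b at -0.41 and -1.39) and 0.353 for interferon response and MHC class I (Rtp4 at -0.92). C4b passed as lower without scn_cont_565 (adjusted p = 9.99e-10 by edgeR), while its adjusted p reached 0.903 over its other alternatives. For neuronal lists the adjusted p was 0.725 for GABA genes (Gabra5 and Gabra3 at 0.39 and 0.51) and 0.725 for synaptic vesicle genes (Sv2c and Pclo at 0.51 and -0.35). Other cell types gave 0.714 for oligodendrocyte precursors (Olig1 and Lhfpl3 at -0.39 and 0.28), 0.130 for endothelium and pericytes, 0.960 for choroid plexus (Enpp2 and Prlr at -0.37 and 0.27) and 0.154 for ependyma and tanycytes (Tm4sf1 and Crym at -0.59 and 0.68). In the endothelium and pericyte list Vtn, vitronectin, fell from 73.9 ± 7.47 to 51.0 ± 1.46 CPM (adjusted p = 0.0420 by edgeR). Vtn lost its call with plain library size, with limma-voom weights and with the myelin list as a covariate. It also lost it without any library other than scn_cont_567, at adjusted p of up to 0.644 over its alternatives. Neighbouring tissues gave 0.199 for striatum, thalamus and cortex, whose 1 member past is Rora, 0.725 for pituitary (Chgb and Cga at -0.13 and 0.58) and 0.454 for blood cells (Alas2 and H2-Aa at 0.85 and -0.61). The adjusted p was 0.0762 for heat shock and unfolded protein genes (Rbm3 and Hsph1 at 0.61 and 0.22), 0.725 for nuclear oxidative phosphorylation genes (Ndufb2 and Ndufb4 at 0.19 and 0.34), 0.239 for mitochondrially encoded genes (mt-Co1 and mt-Nd4 at -0.17 and -0.15) and 0.745 for cytosolic ribosomal proteins (Rpsa and Rpl3 at -0.20 and 0.14). For genes around Gpnmb on chromosome 6 it was 0.762 (Mpp6 and Osbpl3 at -0.39 and 0.39), and for pigment cell genes, of which 2 were measured, it was 0.375 (Slc24a5 and Mitf at -0.23 and -0.31).

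Some of these 18 lists passed when a library was left out. Without scn_cont_565, which brought the lists past the threshold from 7 to 11, these were heat shock and unfolded protein genes (higher, adjusted p = 0.00385, camera), ribosomal proteins (higher, 8.39e-04), interferon response and MHC class I (lower, 0.0445) and complement (lower, 0.0181). Heat shock genes also passed without scn_glauc_154 (0.00122), and interferon response (lower, 0.0451) and blood cells (higher, 0.00331) without scn_glauc_152. Endothelium and pericytes passed without scn_cont_567 (lower, 0.0218) and synaptic vesicle genes without scn_glauc_153 (lower, 0.0458). The ependyma and tanycyte list was higher without scn_cont_567 (0.0148) or scn_glauc_153 (0.00107) and lower with the myelin list as a covariate (0.00774). With that covariate heat shock genes (higher, 0.0307), interferon response (lower, 7.26e-06) and complement (lower, 0.0356) passed too. Heat shock genes also passed with plain library size (0.0434) and complement with a mean of at least 10 CPM (0.0249).

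**Figure D4:**
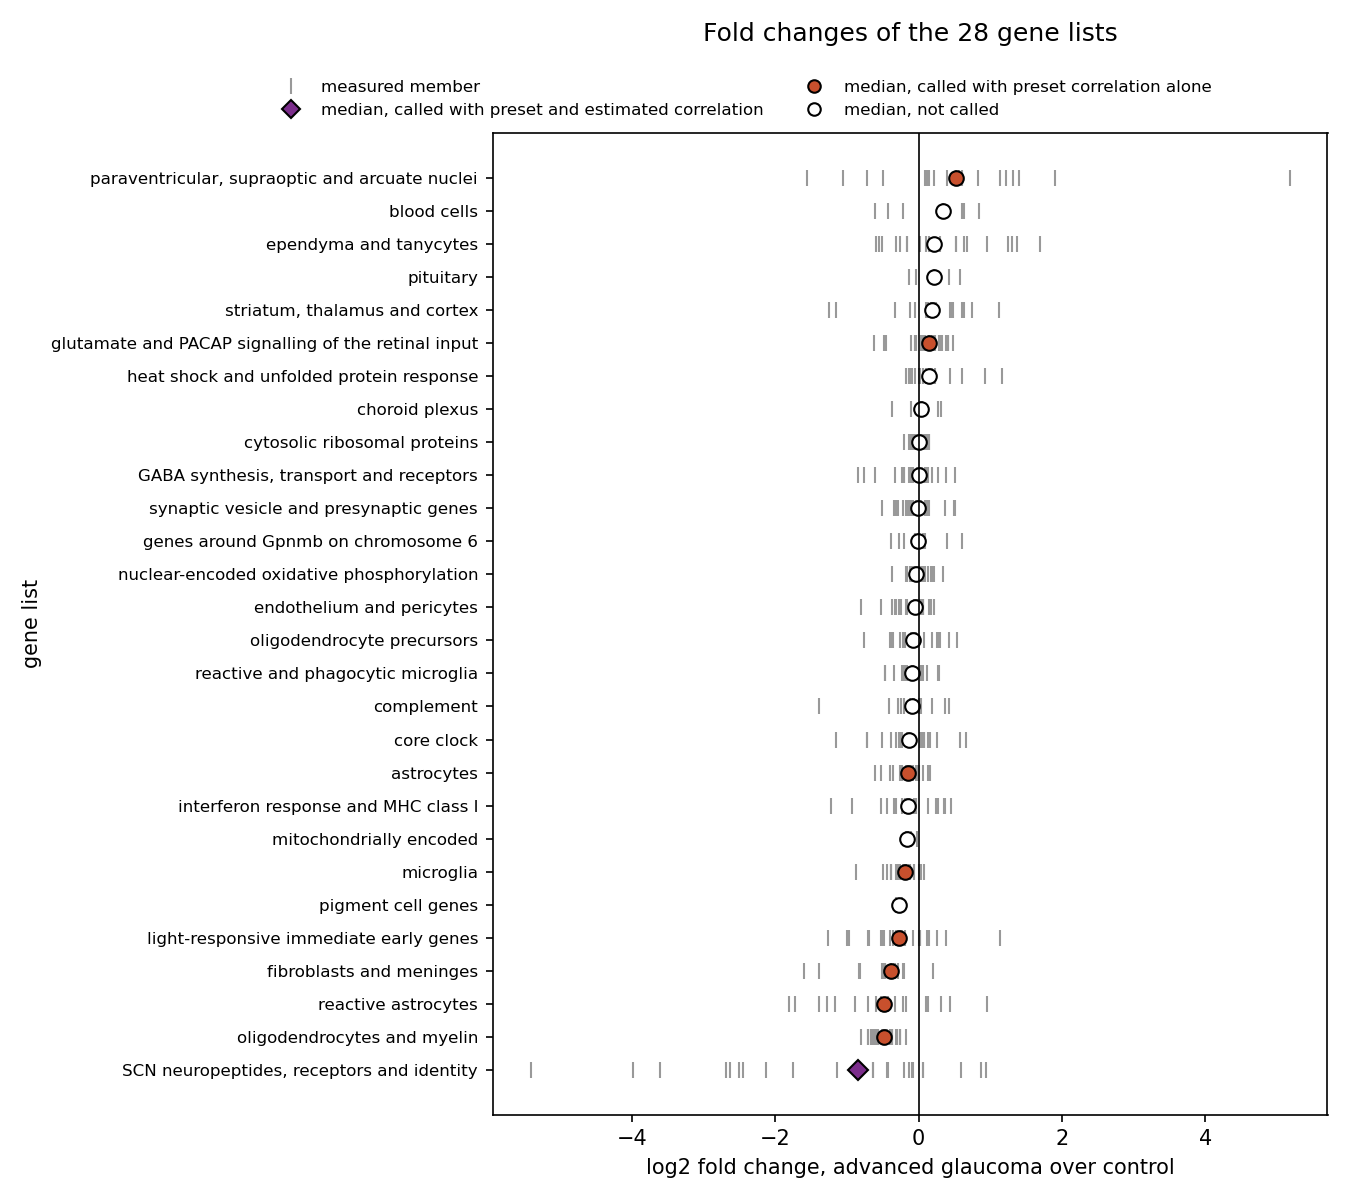
Log2 fold change of advanced glaucoma over control for the measured members of 28 gene lists, with 1 tick per gene and the list median as a marker coloured by its camera call. The SCN list has the lowest median, -0.84, and is the list called with both the preset and the estimated correlation.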

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

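Within the 4 control libraries, 9 of 110 values examined had 1 library far from the other 3 by Dixon's test, where chance flags about 1 in 20. Library scn_cont_565, the shallowest library, was the distant one in 6 of them. It had 35.7 CPM of Arntl against 17.5 to 20.1 in the other controls, 188 CPM of Dbp against 135 to 140, and 13.4 CPM of the cold-inducible gene Rbm3 against 9.005 to 9.49. It also had 517 CPM of Cga, the alpha subunit of pituitary glycoprotein hormones, against 15.1 to 57.5. Its mt-Nd4 was at 11324 CPM against 7615 to 8122, and its Rpl3 at 1223 CPM against 1017 to 1052.

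Library scn_cont_570 had 17.8 CPM of Npy2r against 23.3 to 23.9 in the other controls. It also had 232 CPM of Id4 against 188 to 189. Library scn_cont_567 had 17.4 CPM of H2-Aa, a class II histocompatibility gene, against 5.20 to 5.58.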

How the results depend on the processing

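None of the 40 named genes that passed was called in the opposite direction under any alternative. The ependyma and tanycyte list, higher but short of the threshold in the main test (adjusted p = 0.154), was higher and past it without scn_cont_567 or scn_glauc_153 (0.0148 and 0.00107) and lower and past it with the myelin list as a covariate (0.00774). The SCN list stayed lower and past the threshold in each alternative, at adjusted p of 1.33e-20 to 0.0393, while its members called lower ranged from 6 to 15 against 12. Changed genes numbered 66 in the main test and 60 to 91 with RLE factors, plain library size, a mean of at least 10 CPM, DESeq2 or limma-voom. They numbered 202 with no filter on low counts (94 higher, 108 lower, all 66 shared, 194 of them genes that the main test also tested) and 15 with the myelin list as a covariate (11 shared), and 28 to 93 when each library was left out (28 without scn_glauc_154, 33 without scn_cont_570). That covariate had a correlation of -0.69 with the group, so it removes part of the group difference; the cause of the higher count with no filter was not tested. The core clock list passed with a mean of at least 10 CPM (0.00590, 20 members left), and over the libraries left out its adjusted p ran from 0.0368 to 0.443; the light-responsive list gave 0.266 with an estimated correlation. Other lists past the threshold numbered 0 with an estimated correlation and 6 to 11 with a library left out. Of 40 named genes that passed, 11 kept their call in each alternative that used all 7 libraries and 9 also with each library left out: Rgs16, Rasl11b, Rora, Nms, Vgf, Prokr2, Igfbp5, Lhx1 and Six6. Of 62 that did not pass, 16 passed in some setting. Sex as a covariate was not run, since the sex-linked genes showed 1 sex. Genes near the floor, such as Gpnmb, give no fold. With each library thinned to 2174456 counts, 61 genes changed, 49 of them shared.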

Other observations

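The tests of a caudal gene list and of unequal peptide falls were chosen only after the group difference was seen, and so were the names Zic1, Zic2, Zic5, Bsx, Gsx1, Pomc and Agrp. Zic2 and Zic5, which encode zinc finger factors expressed in the anterior forebrain midline and optic chiasm region, had lower values together. The first fell from 11.3 ± 2.25 CPM in control to 3.20 ± 1.15 CPM in advanced glaucoma (SD, n = 4 and n = 3; adjusted p = 0.00884 by edgeR), and the second from 13.6 ± 5.07 to 2.72 ± 0.534 CPM (adjusted p = 7.20e-04). Both lost their calls with the myelin list as a covariate, and Zic2 also without scn_cont_570 or scn_glauc_154. Zic1 was at 46.8 ± 17.5 and 13.2 ± 7.97 CPM and did not pass (log2 fold change -1.79, adjusted p = 0.433). Peptides of nuclei around the SCN varied widely within groups: Agrp ran from 0.720 to 53.9 CPM over the control libraries and from 16.4 to 91.6 CPM over the advanced glaucoma ones. Oxt, oxytocin, ran from 1152 to 2441 CPM in control and was at 161 CPM in scn_glauc_154 and at 974.5 and 1460 CPM in scn_glauc_152 and scn_glauc_153 (log2 fold change -1.06, adjusted p = 0.851 by edgeR). Cartpt was at 198 ± 147 and 519 ± 229 CPM (adjusted p = 0.729).

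SCN genes fell in advanced glaucoma while Nkx2-1 was higher, and Pmch and Ghrh had higher values that did not pass in the main test but did with DESeq2 (adjusted p = 4.09e-08 and 0.0165) and without scn_glauc_153 (6.24e-04 and 0.0370), in ranges of 4.09e-08 to 0.483 and 6.79e-06 to 0.552 over their alternatives. Library depth is argued against, since 12 of the 12 SCN genes called lower kept their call after each library was thinned to 2174456 counts. An equal loss of all SCN cells, with no other source of their transcripts in the piece, stays open. Vip, Grp, Nms, Prok2 and Prokr2 fell by unequal folds (exact permutation p = 0.0286, the smallest the 35 splits can give). But this set of genes was put together after their folds were seen, so that p does not decide. Nor could it speak against an equal loss if other tissue in the piece also held these transcripts. Another candidate explanation that stays open is a tissue piece taken further caudal with less SCN. A list of tuberal, lateral and mammillary genes was written without the single genes already seen as higher. It was higher as a set (camera p = 0.0323 with an estimated correlation, not adjusted over other lists). But this list too was written after the group difference was seen, so its p does not decide either. Of its 20 genes, 13 were measured. The median log2 fold change of the list was 0.82, with a 95% interval of 0.21 to 1.31 from resampling the 13 measured genes. That interval treats the genes as independent and holds no spread between mice. By sign 12 of the 13 measured members were higher, though 0 passed alone in the main test and several hardly rose. Tac2, Foxb1 and Pomc had log2 fold changes of 0.09, 0.19 and 0.21, and that of Lhx5 was -0.35. Hcrt was high in scn_glauc_153 alone, at 59.7 CPM against 6.50 in scn_glauc_152, 1.66 in scn_glauc_154 and 3.47 to 15.9 in control. Strain differences linked to Gpnmb stay open as well: 0 of the 66 changed genes lay within 10 Mb of it, but chance alone gives 0.494 and 0 members of the SCN list lie there, so that count cannot speak against an effect at a distance. An effect of the disease on SCN cells stays open too and untested. The position of each piece, the time of day, the age and the library batch were not given in the sources used here. Any of these that differed between the groups could not be told apart from the disease.

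In that caudal list, 4 of the 13 measured genes, Hcrt, Agrp, Tac2 and Pomc, also stand in the fixed list of the paraventricular, supraoptic and arcuate nuclei. That fixed list passed as higher with the preset correlation, so part of the caudal list is not independent of it. The SCN region may also express some of the genes at a low level, so the camera p of 0.0323 is not specific to other nuclei. The members with the smallest p were Gsx1 (0.947 ± 0.841 CPM in control and 4.84 ± 1.03 CPM in advanced glaucoma) and Bsx (1.85 ± 0.929 and 12.2 ± 9.93 CPM), with adjusted p of 0.0600 and 0.0628 in the main test. Over the alternatives Gsx1 ran from 0.00881 to 0.757 and passed with no filter on low counts, with limma-voom and without scn_cont_567 (0.0201). Bsx ran from 8.14e-10 to 0.785 and passed with plain library size, with no filter, with DESeq2 and without scn_glauc_153 (0.00102). Its abundant member Pomc was at 23.6 to 223 CPM in control and 93.5 to 178 CPM in advanced glaucoma.

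Over the 35 splits of the 7 libraries into 4 and 3, chance is argued against for the changed genes, though not excluded. Only 1 split, the real one, gave as many as 66, and the highest other gave 20. Chance is argued against for the SCN list too, with 1 split at a camera p as small as 6.83e-18 and 7.61e-10 as the lowest other, with a preset correlation. For the light-responsive list 1 split, the real one, gave a camera p of 1.01e-04 or lower, and the lowest other was 4.16e-04. That argues against chance only for the test with a preset correlation, since the call is lost with an estimated one (adjusted p = 0.266). A share of 1 in 35 is the smallest that these splits can give, so they cannot exclude chance for any of these results. Chance is not argued against for the core clock list, where 9 splits gave a p as small as 0.0446 and the lowest was 0.00320. Nor is it argued against for the count of other lists, where 10 splits gave 7 or more past the threshold and the highest other gave 12.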
